A study of Homo sapiens with 9 samples.

How the data were processed

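RNA from blood-forming cells made from H1 human embryonic stem cells was sequenced as strand-specific libraries with paired reads, per the labels' protocols. The values analysed were the authors' deposited counts, whole numbers of reads per gene symbol in 1 table of 9 libraries. Per the submitters' processing notes, HISAT2 and featureCounts were used with the hg38 build, and their versions, settings, annotation and use of strand are not given in the sources used here. Counts were therefore read as reads assigned to a symbol, with no correction by the authors for depth. Genes that share sequence with near-identical copies (ribosomal protein genes and their pseudogenes, HLA, globin, histone and gonadotropin genes) and genes that overlap a neighbour are uncertain, since multiply mapped reads may be dropped or split.

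Samples were grouped by the labels' genotype and surface marker into 3 groups of 3. Replicate libraries were compared first by a chi-square of their counts over genes with at least 20 counts, which gave 3.96 to 7.84 per degree of freedom within groups, so no pair was the same library within sampling noise. Of the 21229 genes, 80 had 0 counts in every library. All 9 columns were used.

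The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM factors, genes kept by filterByExpr (minimum count 10, minimum total 15) and a model of group means over all 9 libraries, without a block. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The common dispersion was 0.00452, a biological coefficient of variation of 6.72%. TMM factors averaged 0.876 in CD38+ control, 1.16 in CD90+ control and 0.980 in GATA2 overexpression CD90+ libraries, so fold changes depend on the scaling. Standard errors were the log2 fold change divided by the square root of F. Where a group had 0 counts for a gene, a bound was computed from a floor of 3 counts over the group, and where it had 1 to 3 counts the ratio is given with an exact binomial (Clopper-Pearson) 95% interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The floor was 0.0261 CPM in CD38+ control, 0.0193 CPM in CD90+ control and 0.0265 CPM in GATA2 overexpression libraries.

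The design, the alternatives, the rule for named genes and 34 gene lists were fixed before the data were examined. The lists cover blood lineages, stem cell and endothelial programmes, non-blood cells, cell cycle, stress, metabolism, ribosomal proteins, signalling and surface markers. Of 940 list symbols, 908 matched the table directly, 12 through a RefSeq synonym, and 20 were not analysed here. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. Fry tests whether the genes of a list move on balance to the same side, and does not compare the list with other genes. Named genes were 6 fixed genes (GATA2, THY1, CD38, CD34, PTPRC, SPN), the 5 largest rises and 5 largest falls in each main comparison (3 and 3 in the further comparison) among called genes with libraries that did not overlap and a mean of at least 5 CPM, and members with the lowest adjusted p of the lists. For the first 8 lists by camera p up to 3 members were named and 1 in the other direction, and for further lists up to 2. Positions are from GENCODE release 29 on GRCh38.

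The procedure was tested on simulated data, with 4 draws per comparison of counts for 16232 genes from the real means, library sizes and gene-wise dispersions, and 200 genes changed. For CD90+ against CD38+ control, 46.5%, 63.5%, 73.5% and 93.5% of genes changed 1.25-fold, 1.5-fold, 2-fold and 4-fold were called in the right direction. For GATA2 overexpression against control CD90+ the shares were 50.0%, 58.0%, 76.5% and 92.5%, and for GATA2 overexpression against CD38+ control 38.0%, 56.0%, 75.5% and 92.0%. A first version of this test required over 80% recovery of 2-fold changes among all genes and failed. The missed genes were those with few counts, as 98.3%, 99.2% and 100% of 2-fold changes at or above 5 CPM were recovered in the 3 comparisons and 36.2%, 32.4% and 30.0% of those below it, so the requirement was set for genes at or above 5 CPM. False calls were 7.60%, 6.53% and 5.96% of all calls in the 3 comparisons, above the nominal 5%, and 5.60%, 5.08% and 3.66% when counts were drawn from trended dispersions. Small changes in genes with few counts were therefore missed in these draws. The adjusted p was slightly too small with gene-wise dispersions, but not in every comparison with trended ones. In the data 13056, 12602 and 13498 genes were called, far more than the 200 changed per draw. The simulated shares may therefore not carry over to the real calls.

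Alternatives were RLE size factors, library size only, upper-quartile factors, no filter or at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma voom, a fit on the 2 groups compared, a replicate block, stricter thresholds and leaving out each library. Removal of a trend in transcript length and GC content (fitted per library on GENCODE transcripts) was added after the data were seen. In data simulated with a linear trend in log2 transcript length only, that step returned a median log2 fold change of 0.99 for ribosomal protein genes raised by 1. A trend in GC content was not simulated, so its removal was not tested.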

Results

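Expression was measured by strand-specific RNA sequencing in blood-forming cells differentiated from H1, an established line of human embryonic stem cells. The 9 libraries fell into 3 groups of 3. These were control cells positive for the surface antigen CD38, control cells positive for CD90 (the product of THY1), and CD90+ cells that overexpressed the transcription factor GATA2. Read counts assigned to genes totalled 42695005 to 45561088 per library in CD38+ control cells, 42577569 to 47261093 in CD90+ control cells and 37500192 to 39582736 in GATA2 overexpression CD90+ cells. Of 21229 genes in the table, 16232 passed the filter on low counts and were tested. Levels are CPM, scaled by library size and TMM factors and given as mean ± SD with n = 3 for each group, and calls are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p under 0.05).

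Libraries of the same group had Spearman correlations across genes of 0.995 to 0.997, against 0.886 to 0.942 between groups. Genes are not independent replicates, and nothing in the labels says whether the libraries of a group came from separate cultures. The p-values therefore measure the spread between these samples only, which may be technical. The first principal component held 77.9% of the variance among the 500 most variable genes and separated CD38+ from CD90+ cells. The second held 20.4% and separated control from GATA2 overexpression CD90+ cells.

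**Figure D1:**
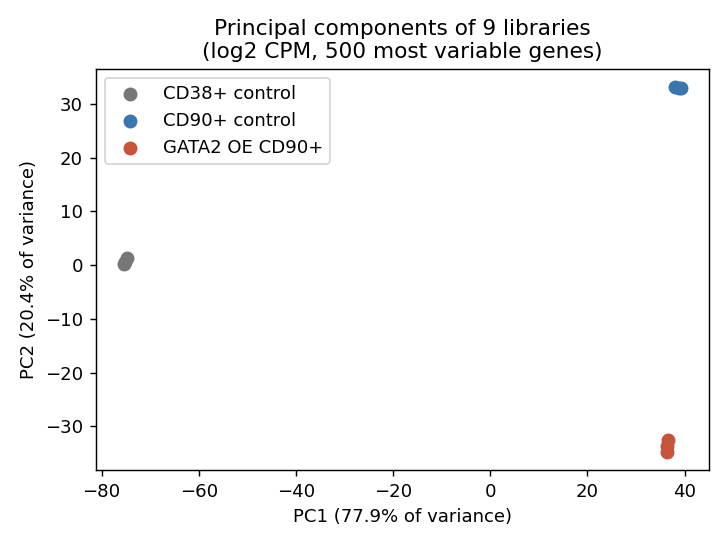
First and second principal components of log2 CPM over the 500 most variable genes, with 1 point per library and the share of variance in percent on each axis. The 3 groups of 3 libraries lie apart, and the first component (77.9%) parts CD38+ control from the other groups.

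The levels of GATA2 and of the sorted surface markers came first, since they bear on the labels. GATA2 (ENSG00000179348.11, chromosome 3, 128479427 to 128493185, minus strand, GRCh38) was at 376 ± 12.8 CPM in GATA2 overexpression CD90+ cells, 87.3 ± 1.93 CPM in CD90+ control cells and 569 ± 16.3 CPM in CD38+ control cells. It was 4.31-fold higher with overexpression than in control CD90+ cells (adjusted p = 1.34e-18), yet 1.51-fold lower than in CD38+ cells (adjusted p = 3.30e-12). The counts do not separate a transgene from the endogenous gene. THY1 (ENSG00000154096.13, chromosome 11, 119417378 to 119424985), which encodes CD90, had 0 counts in the 3 CD38+ libraries and 4.43 ± 0.632 CPM in CD90+ control cells. This was at least 169-fold higher, taking 3 counts over the CD38+ group as the floor. CD38 (ENSG00000004468.12, chromosome 4, 15778275 to 15853230) was at 122 ± 2.40 CPM in CD38+ cells, 4.37 ± 0.382 CPM in CD90+ control cells and 2.23 ± 0.514 CPM with GATA2 overexpression.

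**Figure D2:**
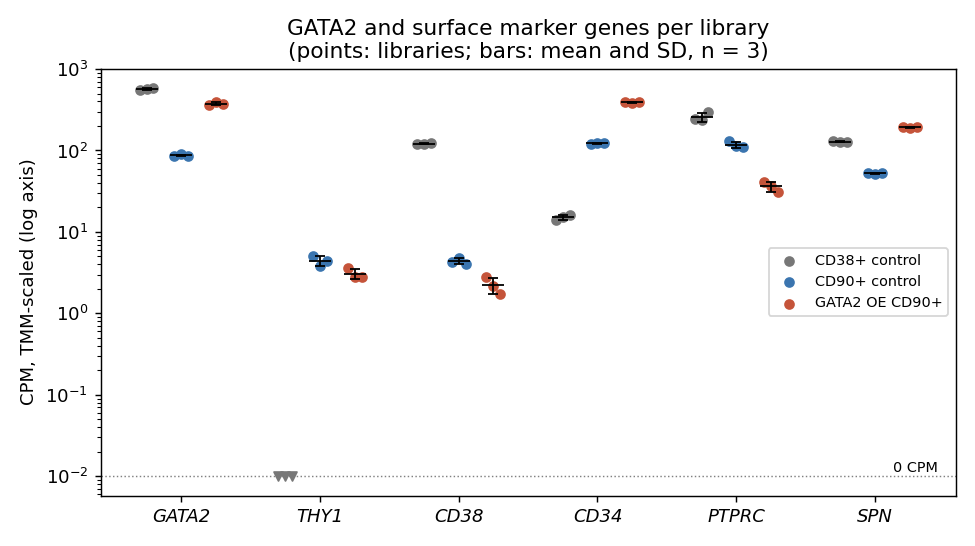
CPM of 6 genes in each of the 9 libraries on a log axis, with points for libraries and bars for the mean and SD (n = 3). GATA2 lies at 569 CPM in CD38+ control, 87.3 CPM in CD90+ control and 376 CPM in GATA2 overexpression CD90+ cells, and THY1 is drawn at a dotted line for 0 CPM in CD38+ control.

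The comparison of CD90+ with CD38+ control cells asked how the control fraction positive for CD90 differs from the fraction positive for CD38. Control CD90+ cells had much lower levels of mast cell, basophil and eosinophil genes, of unfolded protein response genes and of p53 targets. They had higher levels of mesenchymal, epithelial and endoderm, megakaryocyte, erythroid and endothelial genes and of immediate early genes. CD34, a surface antigen of haematopoietic progenitors and endothelium (ENSG00000174059.16, chromosome 1, 207880972 to 207911402), was 8.08-fold higher in CD90+ cells (122 ± 0.699 against 15.1 ± 1.18 CPM, adjusted p = 1.13e-19). PTPRC, the pan-leukocyte antigen CD45 (ENSG00000081237.19, chromosome 1, 198638457 to 198757476), was 2.19-fold lower, at 118 ± 10.7 against 257 ± 32.4 CPM. SPN, the leukocyte antigen CD43 (ENSG00000197471.11, chromosome 16, 29662979 to 29670876), was 2.43-fold lower, at 52.5 ± 0.542 against 128 ± 1.83 CPM.

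Of the mast cell, basophil and eosinophil list, 19 of 24 tested genes fell and 4 rose in CD90+ cells (the same counts when adjusted over the list alone), with a median log2 fold change of -3.57. HDC, which makes histamine, fell 41.5-fold from 1300 ± 18.7 to 31.4 ± 0.504 CPM. ALOX5AP, needed for leukotriene synthesis, fell 37.6-fold, and CSF2RB, the shared receptor chain for IL-3, IL-5 and GM-CSF, fell 24.1-fold. PRG3, an eosinophil granule protein gene, went the other way, at 74.3 ± 0.447 against 2.66 ± 0.167 CPM. Granulocyte precursor genes fell in 15 of 24 cases and rose in 8, and S100A9 fell 8.10-fold from 2645 ± 37.8 CPM. Among the genes with the largest falls were CCL13, with 1 count over the CD90+ libraries (ratio 2212, 95% counting interval 396 to 87418), IL9R (330-fold), PRF1 (201-fold), IL3 (181-fold) and KRT79 (171-fold).

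The unfolded protein response list fell in 19 of 20 genes and rose in 0, also when adjusted over the list alone, with a median log2 fold change of -1.33. The chaperone HSPA5 fell 4.02-fold from 3810 ± 51.4 to 949 ± 17.3 CPM, TRIB3 fell 13.8-fold and DNAJB9 fell 4.45-fold. Of 21 p53 targets 19 fell and 1 rose, among them the cell cycle inhibitor CDKN1A, which fell 2.99-fold from 1293 ± 34.5 CPM, BTG2 and SESN2. G2/M genes fell in 45 of 52 cases and rose in 2 (median log2 fold change -0.46, NDC80 2.19-fold lower), and this median was -0.05 when scaled by library size only. Immediate early and heat shock genes rose in 20 of 28 cases and fell in 6. FOS rose 11.3-fold to 4666 ± 36.2 CPM, DUSP1 rose 5.34-fold and EGR1 rose 3.65-fold, whereas ATF3 fell 1.74-fold.

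Non-blood transcripts were abundant in CD90+ control cells. Of 26 mesenchymal genes 23 rose and 0 fell (23 and 1 when adjusted over the list alone), with COL3A1 at 399 ± 3.29 against 1.49 ± 0.138 CPM and COL1A1 at 180 ± 3.15 against 0.852 ± 0.0776 CPM. THY1, the gene of the sorted antigen CD90, is a member of the mesenchymal list, so it is not independent evidence there. Epithelial and endoderm genes rose in 16 of 20 cases and fell in 3, and KRT19 reached 161 ± 2.37 against 17.8 ± 1.13 CPM. The largest rises were POSTN (at least 473-fold, with 0 counts in CD38+ cells), MYL7 and HAPLN1 (3 and 2 counts in CD38+ cells, ratios 1077 and 994 with 95% counting intervals of 368 to 5226 and 275 to 8216), FGG (2 counts, ratio 580, interval 160 to 4796) and GPC3 (457-fold). Neural genes rose in 11 of 14 cases and fell in 0 (adjusted p = 0.0549 with an estimated correlation and 0.0778 with library size only).

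Blood lineage lists moved beside them. Megakaryocyte genes rose in 18 of 23 cases and fell in 4, with the platelet chemokine PF4 at 1077 ± 1.52 against 69.2 ± 4.63 CPM. THBS1 fell 5.65-fold. Erythroid genes rose in 28 of 32 cases and fell in 2, and HBZ, an embryonic globin gene, rose 32.6-fold. Endothelial genes rose in 21 of 26 cases and fell in 2, with KDR, the VEGF receptor gene, 24.5-fold higher. Of the stem cell programme list 16 of 25 genes rose and 6 fell (16 and 7 when adjusted over the list alone), including the transcription factor genes MEIS1 (8.37-fold higher) and MYCN (9.98-fold higher). Wnt signalling genes rose in 20 of 23 cases, pluripotency genes in 11 of 14 and antigen presentation genes in 12 of 22, and they fell in 2, 2 and 5 cases. CD74, the invariant chain of class II molecules, rose 5.92-fold to 934 ± 5.05 CPM. These rises stood beside those of the mesenchymal, epithelial and neural markers in the same libraries. For the other lists called by camera the counts adjusted over the list alone were the same as over all genes.

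In all, 13056 genes were called, 6679 higher and 6377 lower in CD90+ cells, and 5871 of them differed at least 2-fold (3663 higher, 2208 lower). Camera, with a preset correlation of 0.01 between genes, called 19 of the 34 lists (13 up, 6 down), and 15 of these held with an estimated correlation. Besides the neural list, ribosomal protein genes (55 rose and 14 fell of 78; adjusted p = 0.410 with an estimated correlation), interferon response genes (17 rose and 8 fell of 27; adjusted p = 0.104 with an estimated correlation) and oxidative phosphorylation genes (31 fell and 4 rose of 38; adjusted p = 0.427 with an estimated correlation) lost the call. The oxidative phosphorylation call also ended with RLE factors (adjusted p = 0.0503) and with the length and GC trend removed (0.214), and it was not called with library size only (0.762), where its median of -0.28 became 0.13. Scaling by library size only moved the median log2 fold change of all genes by 0.41 and put 71.2% of calls on the higher side, against 51.2% with TMM factors, and upper-quartile factors moved it by 0.26 and put 64.3% there. With library size only the medians of p53 targets, immediate early, interferon response, antigen presentation and ribosomal protein genes went from -1.23, 0.77, 0.67, 0.58 and 0.25 to -0.82, 1.18, 1.08, 0.99 and 0.66, and ATF3, NDC80 and PTPRC from log2 fold changes of -0.80, -1.13 and -1.13 to -0.39, -0.72 and -0.72. The ribosomal protein median was 0.42 with the length and GC trend removed.

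The comparison of GATA2 overexpression with control CD90+ cells asked how the groups differ within the CD90+ fraction. As separate cultures are not documented, an effect of added GATA2 cannot be told apart from a difference between cultures. A difference in which cells carried CD90 cannot be told apart from it either. Macrophage genes had the lowest median log2 fold change of the 34 lists (-3.11), with the complement genes C1QA, C1QB and C1QC down 229-fold, 321-fold and 353-fold. Ribosomal protein, oxidative phosphorylation, G2/M and G1/S genes rose, with median log2 fold changes of 0.95, 0.78, 0.55 and 0.50 (0.70, 0.54, 0.30 and 0.25 with library size only). Stem cell programme genes and the haematopoietic transcription factor set rose, while immediate early, inflammatory, adhesion, Notch and mesenchymal genes fell. CD34 rose 3.18-fold, to 389 ± 3.12 from 122 ± 0.699 CPM (adjusted p = 1.69e-17), and SPN rose 3.67-fold, to 193 ± 1.85 CPM. PTPRC fell 3.23-fold, to 36.4 ± 5.09 CPM, and CD38 fell 1.96-fold. THY1 was at 3.06 ± 0.439 against 4.43 ± 0.632 CPM (adjusted p = 0.0149), a call lost without CD90+ control replicate 1 (adjusted p = 0.0796) or without GATA2 overexpression replicate 3 (adjusted p = 0.0505), and its adjusted p ranged from 0.00112 to 0.0796 over 18 alternatives.

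Monocyte and macrophage genes fell in 23 of 26 cases and rose in 0 (the same when adjusted over the list alone), with a median log2 fold change of -3.11. C1QA fell from 150 ± 2.08 to 0.654 ± 0.154 CPM, and C1QC from 138 ± 4.71 to 0.390 ± 0.141 CPM. The lysosomal protease gene CTSB fell 4.87-fold, from 1399 ± 2.26 to 287 ± 5.94 CPM. TIMD4, a phosphatidylserine receptor of resident macrophages, and SDS were the other genes among the 5 largest falls, at 193-fold and 187-fold. Inflammatory NF-kB genes fell in 20 of 24 cases and rose in 2, with TNFAIP3 down 8.39-fold. Adhesion and homing genes fell in 22 of 30 cases and rose in 7. The chemokine receptor gene CCR1 fell 22.8-fold, ITGB7 32.4-fold and ITGB2 2.94-fold, and CD47 rose 1.77-fold. Antigen presentation genes fell in 13 of 22 cases and rose in 1, with CD74 down 7.93-fold.

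Ribosomal protein genes rose in 77 of 78 cases and fell in 0, with a median log2 fold change of 0.95. Their share of all counts was 8.09 ± 0.0751% with GATA2 overexpression against 4.90 ± 0.0228% in control CD90+ and 2.98 ± 0.0949% in CD38+ cells. RPS3 rose 2.31-fold to 3251 ± 23.2 CPM, RPL29 2.28-fold and RPL7A 2.13-fold, though reads of these genes can be shared with processed pseudogenes. Oxidative phosphorylation genes rose in 36 of 38 cases and fell in 0, with UQCRFS1, NDUFB10 and SDHC up 1.97-fold, 2.07-fold and 1.93-fold. G2/M genes rose in 43 of 52 cases and fell in 6, and G1/S genes rose in 37 of 43 and fell in 2. In the same libraries macrophage and mesenchymal markers fell. UBE2C rose 3.29-fold to 869 ± 6.60 CPM, CDK1 2.21-fold, PCNA 2.23-fold and TYMS 2.40-fold. CKAP5 and ATAD2 fell 1.51-fold and 1.49-fold.

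The set of haematopoietic transcription factors that includes GATA2 rose in 11 of 15 genes and fell in 1. As GATA2 was itself overexpressed it is not independent evidence there, and GATA1 rose 3.96-fold, from 66.6 ± 3.27 to 264 ± 7.32 CPM. The stem cell programme list rose in 18 of 25 genes and fell in 5, with MYB up 3.51-fold and GFI1B 3.10-fold. Mast cell, basophil and eosinophil genes rose in 17 of 24 cases and fell in 6, and PRG3 rose 3.87-fold. Megakaryocyte genes rose in 13 of 23 cases and fell in 6, with NFE2 up 3.54-fold and THBS1 down 2.18-fold. The largest rises were the gonadotropin subunit genes CGB5 (125-fold, though its reads may be shared with near-identical copies) and CGA (36.5-fold, to 97.3 ± 10.9 CPM), NCR2 (12.7-fold), PRTN3 (12.1-fold, 64.1 ± 21.1 CPM) and TTLL10 (10.3-fold).

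Mesenchymal genes fell in 24 of 26 cases and rose in 1 when GATA2 was overexpressed, with COL3A1 down 4.98-fold to 80.1 ± 0.271 CPM, TGFBI 6.23-fold and COL1A1 5.32-fold, while LOX rose 2.86-fold. Notch and arterial genes fell in 18 of 20 cases and rose in 1, and NRP1 fell 16.2-fold. TGF-beta and BMP signalling genes fell in 21 of 24 cases and rose in 2. Immediate early and heat shock genes fell in 19 of 28 cases and rose in 7, with NR4A2, SOCS3 and ATF3 down 4.09-fold, 7.07-fold and 4.28-fold and MYC up 2.23-fold. p53 targets fell in 15 of 21 cases and rose in 3, and CDKN1A fell 3.35-fold from 433 ± 1.42 CPM. For each list given here for this comparison, the counts adjusted over the list alone were the same as over all genes.

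In all, 12602 genes were called, 6176 higher and 6426 lower with GATA2 overexpression. Of the 4775 that differed at least 2-fold, 1296 were higher and 3479 lower. Camera called 22 of the 34 lists (11 up, 11 down), and 17 held with an estimated correlation. Lists that lost the call were epithelial and endoderm genes (16 fell and 1 rose of 20; adjusted p = 0.0520 with an estimated correlation), interferon response genes (22 fell and 5 rose of 27, IFI6 and IFITM3 among those that rose; adjusted p = 0.0517 with an estimated correlation), glycolysis genes (21 rose and 8 fell of 31; adjusted p = 0.123 with an estimated correlation and 0.0717 with library size only), cholesterol synthesis genes (13 rose and 6 fell of 24; adjusted p = 0.0851 with an estimated correlation) and the surface markers of the sort (6 rose and 7 fell of 14; adjusted p = 0.0870 with an estimated correlation). The cholesterol call was also lost without GATA2 overexpression replicate 1 (adjusted p = 0.0563) or 2 (0.0510), with RLE factors (0.0507), with the length and GC trend removed (0.0881) and with library size only (0.113), where its median of 0.22 became -0.02. The surface marker call was lost without CD90+ control replicate 1 (adjusted p = 0.0569), 2 (0.0595) or 3 (0.0566) and with library size only (0.0554). Scaling by library size only moved the median of all genes by -0.25 and put 35.5% of calls on the higher side, against 49.0% with TMM factors, and upper-quartile factors moved it by -0.11 and put 42.8% there. With library size only the medians of the haematopoietic transcription factor set, megakaryocyte, glycolysis and surface marker lists went from 0.52, 0.55, 0.41 and -0.09 to 0.27, 0.31, 0.16 and -0.33, and with the length and GC trend removed those of the glycolysis and surface marker lists were 0.24 and -0.42. That step took CD47 and CKAP5 from log2 fold changes of 0.82 and -0.59 to 0.41 and -0.91. The antigen presentation median of -1.06 was -1.72 and -1.81 without GATA2 overexpression replicates 2 and 3.

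**Figure D3:**
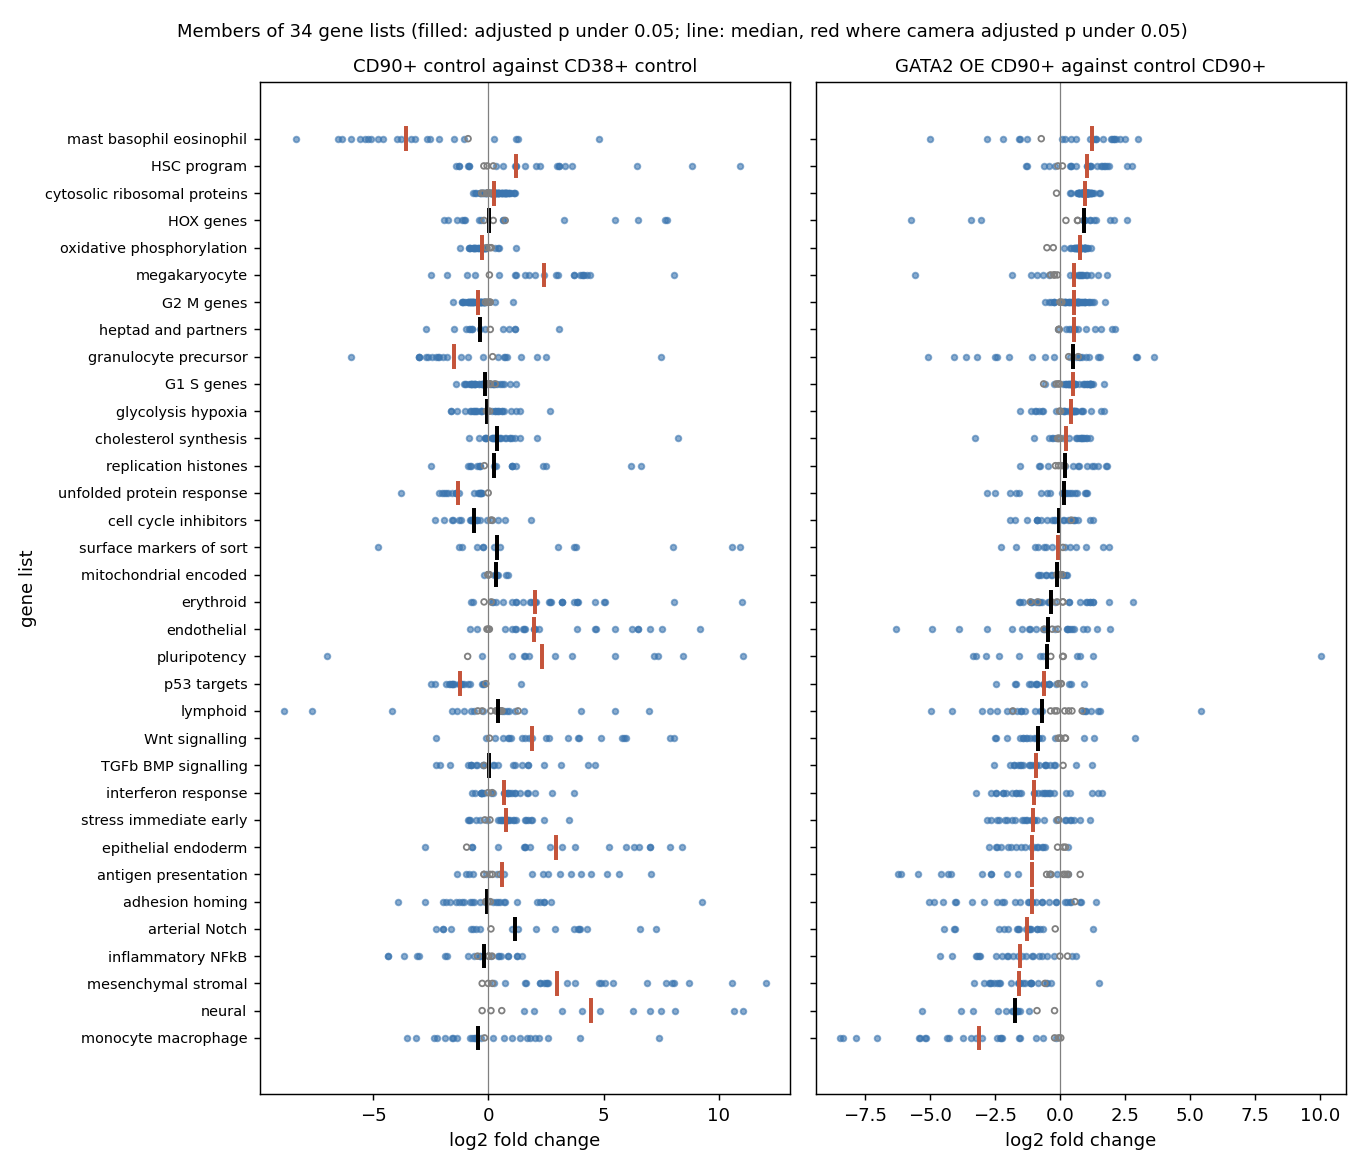
Fitted log2 fold changes of the tested members of 34 gene lists in the 2 main comparisons, with filled points for genes with an adjusted p under 0.05 and open points for the others. Lines mark list medians, red where camera called the list, and the macrophage median lies at -3.11 with GATA2 overexpression. Fitted values of genes with 0 counts in a group depend on the prior count.

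A further comparison set GATA2 overexpression CD90+ cells against CD38+ control cells, which differ in genotype and in surface marker at once. CD34 was 25.6-fold higher (389 ± 3.12 against 15.1 ± 1.18 CPM) and CD38 54.4-fold lower, while PTPRC was 7.06-fold lower and SPN 1.51-fold higher. Ribosomal protein genes rose in 76 of 78 cases and fell in 1, stem cell programme genes rose in 19 of 25 and fell in 4, and megakaryocyte genes rose in 17 of 23 and fell in 4. Monocyte and macrophage genes fell in 24 of 26 cases and rose in 0, mast cell, basophil and eosinophil genes fell in 17 of 24 and rose in 6, and p53 targets fell in 19 of 21 and rose in 0. HAPLN1 (2 counts in CD38+ cells, ratio 644, 95% counting interval 178 to 5320), NCR2 (337-fold) and GRM3 (327-fold) had the largest rises. IL9R had 0 counts with GATA2 overexpression and was at least 1154-fold lower, KLHDC7B was 581-fold lower and IL2RA 533-fold lower. In all, 13498 genes were called, 7026 higher and 6472 lower, and camera called 20 lists (11 up, 9 down), of which 14 held with an estimated correlation. The call was lost for endothelial (adjusted p = 0.0986 with an estimated correlation), erythroid (0.0790), epithelial and endoderm (0.0513), pluripotency (0.0514), oxidative phosphorylation (0.189) and TGF-beta and BMP genes (0.106). The last was also lost without CD38+ control replicate 1 (adjusted p = 0.0511) or GATA2 overexpression replicate 1 (0.0973), 2 (0.0646) or 3 (0.0568), with RLE factors (0.0504), with library size only (0.0513) and with the length and GC trend removed (0.0931). Library size only moved the median of all genes by 0.16 and upper-quartile factors by 0.15, with 58.0% and 57.5% of calls on the higher side, and the G1/S median went from 0.26 to 0.42 with library size only. Adjusted over the list alone, 18 megakaryocyte genes rose, and the other counts given for this comparison were the same. For immediate early genes the list test pointed up with median and mean below 0, and for G2/M genes the median was -0.07 with test and mean up, and 0.09 with library size only; neither list was called.

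Both main comparisons use the control CD90+ libraries, once on each side of the fold, so chance alone gives opposite signs. Of the 10487 genes called in both, 6107 (58.2%) moved in opposite directions. Of 2692 genes that differed at least 2-fold in both, 1902 (70.7%) did, with 1680 higher in control CD90+ cells than in both other groups and 222 lower than in both. Independent lists would give 785 and 176, numbers that take no account of the shared libraries. With library size only, 2191 were higher and 116 lower than in both. Control CD90+ libraries also stood apart in the share of mitochondrial counts, at 6.58% against 4.45% in CD38+ control and 4.74% with GATA2 overexpression. Scaled by library size only, without TMM factors, they had 13723 genes at 1 CPM or more on average, against 12289 and 12542. How these measures bear on the opposite calls was not tested. The Pearson correlation of the fold changes across genes was -0.30, against -0.46 in simulations with no effect. The covariance was -0.90, against -0.03 simulated, a difference of -0.88. In 10 simulated draws with no effect, 0 genes were called in both comparisons, so these draws give no expected share of opposite calls. As independent lists ignore the shared group, opposite calls above their numbers are not by themselves an excess. Part of the opposite calls may come from the shared libraries, which are too few to be split into parts of at least 2. Of 26 mesenchymal genes 22 were higher in control CD90+ than in both other groups. At any size of change, 40 of 52 G2/M genes and 31 of 38 oxidative phosphorylation genes were lower than in both, which depends on the scaling, since with library size only these were 18 and 12, and the medians in CD90+ against CD38+ control went from -0.46 to -0.05 and from -0.28 to 0.13, and the oxidative phosphorylation call there was also lost with an estimated correlation (adjusted p = 0.427).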

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

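The trend removal, and library size only for the overlap of calls, were chosen after the data were seen. Each count of genes or lists called in a comparison stayed within 1.5 times its main value except in these cases. Requiring also a 2-fold change left 5871 genes (3663 higher, 2208 lower) for CD90+ against CD38+ control, 4775 (1296 higher, 3479 lower) for GATA2 overexpression against control CD90+ and 7181 (3735 higher, 3446 lower) for GATA2 overexpression against CD38+ control, by construction. Library size only left 3851 lower genes in the first comparison, as leaving out the TMM factors moved the median log2 fold change of all genes by 0.41. It also took genes at least 2-fold lower in control CD90+ than in both other groups from 222 to 116, and G2/M and oxidative phosphorylation genes lower than in both from 40 and 31 to 18 and 12. Fry called 33, 34 and 32 lists, as it asks another question. Leaving out each library in turn gave 12591 to 12724, 12060 to 12324 and 13163 to 13254 genes, and 19 to 20, 21 to 22 and 19 to 20 lists. Higher genes ranged over 6399 to 6507, 5936 to 6029 and 6833 to 6892, and lower genes over 6171 to 6232, 6091 to 6295 and 6330 to 6362. Genes called in opposite directions in both main comparisons ranged over 5699 to 6018 and in the same direction over 4064 to 4327.

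The replicate numbers of the labels did not pair the samples, as same-numbered libraries had correlations of deviations of -0.09 to 0.03 and 0 of 9 pairs were over 0.1. With a replicate block 12889, 12384 and 13347 genes were called, and 19, 22 and 21 lists. In the last comparison the TGF-beta and BMP list was not called with the block, and the Wnt and surface marker lists were. Of the libraries, 0 of the 9 correlated best with their own number in both other groups. Within a single other group some did, such as CD90+ control replicate 2 with CD38+ control replicate 2 (0.03).

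Over named genes and alternatives 4004 results kept their side of the threshold and, where called, their direction, 34 lost the call, 9 gained it and 3 reversed. Over lists these were 1132, 37, 55 and 0 by the direction of the test. By its sign the median differed in 19 list results, 2 of them of called lists, both with library size only (oxidative phosphorylation in the first comparison, -0.28 to 0.13, and cholesterol synthesis in the second, 0.22 to -0.02). Of named genes not called, 8 results changed sign. FCER1G with GATA2 overexpression against control CD90+ had a log2 fold change of 0.03, not called, which became -0.22 with library size only, -0.0827 with upper-quartile factors and -0.22 with the length and GC trend removed. The changes with library size only and with upper-quartile factors match the shifts of all genes there, -0.25 and -0.11. The gene was chosen after its values were seen, and the cause of its change with the trend removed was not tested. Genes below 5 CPM are limited by counts.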

Other observations

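The tests on composition scaling, on macrophage genes and on non-blood genes were chosen after the results were seen; the length and GC test and the splits were set before theirs. Of the 25 stem cell programme genes, 12 rose in control CD90+ over CD38+ cells and again with GATA2 overexpression. Examples, chosen after their values were seen, are the transcription factor genes HLF (0.339 ± 0.0174, 2.72 ± 0.581 and 8.77 ± 0.681 CPM in CD38+ control, CD90+ control and GATA2 overexpression CD90+ cells; SD, n = 3), MECOM (2.23 ± 0.440, 10.6 ± 0.201 and 22.0 ± 1.41 CPM) and MYCN (7.82 ± 0.342, 78.1 ± 0.742 and 256 ± 11.2 CPM). MLLT3 went from 7.64 ± 0.330 to 23.1 ± 1.81 and 84.8 ± 8.01 CPM, and SPINK2 from 0.412 ± 0.143 to 35.7 ± 0.431 and 79.2 ± 0.202 CPM. HOXA9 was at 2.46 ± 0.581 and 2.84 ± 0.429 CPM in the control groups (adjusted p = 0.254, but 0.0265 without CD38+ replicate 2, 0.00248 with library size only and 0.0146 with upper-quartile factors) and rose to 16.8 ± 1.01 CPM with GATA2 overexpression. RUNX1 ran the other way in the first step, at 166 ± 2.71, 92.3 ± 1.75 and 125 ± 2.86 CPM. Its log2 fold changes of -0.84 and 0.44 were -0.43 and 0.19 with library size only, and the second was 0.24 with the length and GC trend removed.

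Of 26 monocyte and macrophage genes, 11 were higher in control CD90+ cells than in both other groups, while 12 fell from CD38+ to CD90+ control and again with GATA2 overexpression. TYROBP was at 1116 ± 26.3, 371 ± 3.14 and 338 ± 2.15 CPM. Among examples of genes highest in control CD90+ cells, chosen after their values were seen, C1QB was at 0.779 ± 0.183, 134 ± 1.76 and 0.414 ± 0.234 CPM and the class II gene HLA-DRA at 1.06 ± 0.278, 53.5 ± 3.82 and 1.20 ± 0.264 CPM in CD38+ control, CD90+ control and GATA2 overexpression CD90+ cells. LYVE1, a receptor of lymphatic endothelium and some macrophages, was at 5.22 ± 0.442, 75.4 ± 1.40 and 5.05 ± 0.887 CPM. Lists not called by camera with GATA2 overexpression included erythroid genes (11 rose and 15 fell of 32, adjusted p = 0.527), HOX genes (12 rose and 3 fell of 18) and lymphoid genes (7 rose and 14 fell of 29, adjusted p = 0.126). HBD, a globin gene that shares sequence with its neighbours, rose 7.08-fold to 2063 ± 213 CPM, and HOXB9 2.60-fold. For erythroid and pluripotency genes the list test pointed up while median and mean were below 0, and for unfolded protein response and granulocyte genes the test and mean pointed down while the median was above 0. The surface markers were called up with a median of -0.09.

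Lists not called in CD90+ against CD38+ control, with camera adjusted p, were cell cycle inhibitors (0.0666), cholesterol synthesis (0.0985), mitochondrially encoded genes (0.113), adhesion (0.122), haematopoietic transcription factors (0.151), macrophage (0.248), G1/S (0.305), Notch and arterial (0.322), glycolysis, NF-kB and lymphoid (each 0.430), histones (0.461), surface markers (0.496), TGF-beta and BMP (0.608) and HOX genes (0.836). Median, mean and test differed in sign for adhesion, macrophage, lymphoid, histone and HOX genes there. The cell cycle inhibitor list was called without CD38+ replicate 1 (adjusted p = 0.0453), cholesterol synthesis with library size only (0.0115), and mitochondrially encoded genes with library size only (0.00557) and with the length and GC trend removed (0.0331). With GATA2 overexpression against control CD90+ they were, besides those above, cell cycle inhibitors (0.0506), neural (0.0535, 12 of 14 fell), endothelial (0.176), HOX (0.176), unfolded protein response (0.177), histones (0.191), mitochondrially encoded (0.193), Wnt (0.240), granulocyte (0.648) and pluripotency (0.714). Cell cycle inhibitors were called there without CD90+ control replicate 3 (0.0466), with RLE factors (0.0361), with library size only (0.00689) and with the length and GC trend removed (0.0286, median 0.11 against -0.04). Mitochondrially encoded genes were called without GATA2 overexpression replicate 1 (0.00621), with library size only (0.0387) and with the trend removed (0.00118), and unfolded protein response genes with library size only (0.00858, median -0.09 against 0.15) and with the trend removed (0.0251).

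The 6 libraries of a comparison split into 3 and 3 in 10 ways, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many genes and as many lists. The real splits gave 13056, 12602 and 13498 genes, and the highest of the other splits 0 by edgeR's quasi-likelihood test, with at most 54, 104 and 148 genes at an unadjusted p under 0.05. The real splits gave 19, 22 and 20 lists and the highest of the others 17, 19 and 17, so the number called hardly separates the real split. The other splits all mix the groups unequally, so part of the group difference remains in them and the spread within each side is larger. Their counts of genes and lists therefore do not show what no difference would give.

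Ribosomal protein and oxidative phosphorylation genes rose with GATA2 overexpression against control CD90+. A trend with transcript length was present (Spearman correlation across genes -0.19 with log2 fold change), and its removal lowered both medians. With that trend and GC content removed, the median log2 fold change of ribosomal protein genes went from 0.95 to 0.71 (95% bootstrap interval over genes 0.67 to 0.75). That of oxidative phosphorylation genes went from 0.78 to 0.63 (0.42 to 0.70), and both lists were still called. These medians argue against the fitted trend as the whole cause. The bootstrap intervals treat genes as independent and may be too narrow. Estimated correlations between genes in the main fit were 0.389 and 0.155 for the 2 lists. With library size only the ribosomal protein median was 0.70 (0.65 to 0.78). That change was fixed in advance, since leaving out the TMM factors moved the median of all genes by -0.25. It shows that the factors account for part of the 0.95, and is no test of which scaling is right. A biological effect of GATA2 stays open as a hypothesis, as do reads shared with pseudogenes and a change in the mix of sorted cells. Macrophage and mesenchymal genes fell in the same libraries (median log2 fold changes -3.11 and -1.56). None of these causes was tested.

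Macrophage genes fell further than non-blood genes with GATA2 overexpression against control CD90+, whereas both would fall by like factors if all non-progenitor cells had been lost alike. The medians differed by -1.55 on the log2 scale (-3.11 over 26 genes against -1.56 over 60), with a permutation p = 2e-05 (two-sided, genes permuted between the lists) and a 95% bootstrap interval over genes of -3.13 to -0.40, which leaves out 0 but reaches differences under 0.5. The criterion was changed from the permutation p, by which equal falls were rejected, to this interval after the result was seen, and as the list was taken up for its low median and both measures treat genes as independent, a loss of all such cells alike, fewer macrophages among the sorted cells and lower expression per cell cannot be told apart here. The interquartile range of the log2 fold changes was 3.64. Among the most abundant members, TYROBP was at 371 ± 3.14 and 338 ± 2.15 CPM and FCER1G at 318 ± 2.46 and 325 ± 8.98 CPM in control and GATA2 overexpression CD90+ cells. CTSB went from 1399 ± 2.26 to 287 ± 5.94 CPM and CSF1R from 1068 ± 14.4 to 228 ± 10.3 CPM. The TYROBP log2 fold change of -0.13 was -0.38 with library size only, -0.25 with upper-quartile factors, -0.23 with the filter at 1 CPM and -0.30 with the trend removed. Of the 26 genes, 24 were at 1 CPM or more in CD38+ cells. Whether macrophages in these cultures carried CD90 was not tested.

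Mesenchymal, epithelial and neural genes in control CD90+ libraries may come from non-blood cells that express CD90 and pass the sort, a hypothesis. Had a single source shrunk with GATA2 overexpression, the 3 lists would have fallen alike, and their medians were -1.56, -1.06 and -1.73, a range of 0.67 (95% bootstrap interval over genes 0.17 to 1.48, a criterion that also replaced the permutation p = 0.138 after the result was seen), so that a single source and several cannot be told apart. Among the most abundant members LUM went from 254 ± 1.23 to 84.1 ± 8.14 CPM, TTR from 82.4 ± 0.641 to 25.2 ± 2.88 CPM and STMN2 from 13.1 ± 0.840 to 3.69 ± 0.330 CPM, while SPARC went from 549 ± 7.32 to 435 ± 10.9 CPM and KRT18 from 315 ± 2.41 to 394 ± 2.52 CPM, at 180 ± 1.47 and 236 ± 4.77 CPM in CD38+ cells (their log2 fold changes of -0.33 and 0.32 were -0.58 and 0.07 with library size only, and that of KRT18 was 0.21 with upper-quartile factors and that of SPARC -0.52 with the trend removed). Of the 26, 20 and 14 genes, 1, 1 and 2 stand in another list and 15, 9 and 2 were at 1 CPM or more in CD38+ cells. Lower expression within the same cells stays open.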
